A study of Homo sapiens with 813 samples.

How the data were processed

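Single-cell RNA-seq was at hand for 813 labelled cells of 5 patients with AML, each with a diagnosis and a relapse sample. The deposited tables, 1 per patient, hold estimated counts of reads per gene and cell, not normalized, made per the submitters' processing notes with STAR and featureCounts on the genome build hg19; versions and options are not given in the sources used here. Their unit was read as estimated counts because 18.5% of the values above 0 were not whole (tolerance 1e-06). Per the labels' protocols, cells were sorted singly into 96-well plates and libraries were made with Smart-seq2, which has no molecular identifiers, so reads are not independent molecules and depth includes amplification.

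Of the labelled cells, 811 had a column whose name matched them and 2 had none. A further 2 columns matched no label and were not used. The tables have 26454 rows. The 92 rows of ERCC spike-in RNA were left out of library sizes and tests; they held 7.17% of all reads. Another 108 rows, genes linked to a sex chromosome that would describe a person, were removed on reading, which left 26254. Gene symbols were those of the tables; 4 list symbols were matched through synonyms in a RefSeq gene table, 14 were not in the tables, 13 of them mitochondrially encoded, and no coordinates were used because the reference at hand was not hg19.

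Cells with at least 1000 genes detected were kept, 664 of 811. No doublet caller was run on these plate-sorted cells; 5 kept cells with over 3 times the median number of genes of their sample were left out in an alternative. Cells were not clustered, since the sort aimed at a single population, although some cells had markers of excluded lineages. They were described by counts of lineage markers fixed before the data were examined. Of the cell columns used, 0 were identical to another.

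Counts were summed over the kept cells of each patient and state and rounded to whole numbers. Genes with at least 5 reads in at least 10% of kept cells that also passed filterByExpr were tested, 7429 in all. The main test was the quasi-likelihood F-test of edgeR 4.0.16 with TMM factors and the model patient plus state; SE is the log2 fold change divided by the square root of F. The biological coefficient of variation was 0.732 with 4 residual degrees of freedom. The patient was a block because the series text describes the diagnosis and relapse samples as matched. As a check, the deviations from the state means of a patient's 2 samples were correlated across genes at over 0.1 in 5 of 5 pairs (0.251 to 0.436). Adjusted p-values are Benjamini-Hochberg values. CPM were computed from the sums with TMM factors and are given as mean and SD over patients.

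Gene lists and marker sets, 31 and 11, and the ribosomal protein genes were fixed before the data were examined. The 33 with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, with an estimated correlation and with fry. Camera compares a list with all other genes; fry asks whether its genes move one way on balance. HOX and MEIS genes, mitochondrially encoded genes and the marker sets of T, natural killer, plasma, dendritic, neutrophil, megakaryocyte, mast and stromal cells had fewer than 3 tested members.

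The text names genes by a rule fixed beforehand. It takes up to 12 genes per direction past the threshold that moved one way in all pairs, filled by smallest unadjusted p and then reported as not passing, then up to 4 members of each list by smallest p, and the genes of the sort. Genes whose level mainly reports a common germline deletion, an HLA haplotype or a leukaemia rearrangement were not named.

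For measures per cell, reads of each cell were thinned without replacement to 100000, which 95.0% of kept cells reach; 631 cells remained and 33 were too shallow, 19 at diagnosis and 14 at relapse. Differences were tested over the 5 patients with a two-sided exact sign-flip test of 32 arrangements. Similarity used the 2000 most abundant genes, and mixing the 10 nearest neighbours in 20 principal components of log2(CPM + 1) of the 2000 most variable genes within a patient. Intervals of shares are exact 95% binomial intervals and cover counting error only.

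The code was tested on simulated sums of the 7429 genes with the real means, library sizes and dispersions. With 50 genes changed by each fold, 22% of 4-fold, 60% of 8-fold, 72% of 16-fold and 98% of 32-fold changes were called, with 4 false calls, and 1 gene was called with no change simulated. With the dispersion divided by 5, 98% of the 4-fold changes were called. A list of 64 genes shifted 2-fold was called by camera (adjusted p = 1.35e-17), and 0 of 33 lists were called with no change; simulated genes vary independently, unlike real ones.

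Alternatives covered the block, scaling (DESeq2 1.42.0 size factors, upper quartile), gene and cell filters, the weight of each cell, thinning, the DESeq2 and limma voom tests, robust edgeR, detection shares, leaving out each patient, and the settings of each measure per cell. Alternatives without possible doublets, without cells with over 50% spike-in reads, without cells showing markers of excluded lineages, and the mitotic gene set were added after the data were seen. With at least 3 markers counted on unthinned reads, 102 of the 664 kept cells had B-cell markers and 264 had markers of any excluded lineage. In 1 sample 84.1% of cells at equal depth had B-cell markers, so few of its cells remained in these fits. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used. The plate or library batch of a cell is not in the labels used here.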

Results

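The series measured messenger RNA in single leukaemia-initiating cells of acute myeloid leukaemia (AML), a cancer of blood-forming cells. The cells were sorted from the bone marrow of 5 patients at diagnosis, before treatment, and again at relapse, after treatment. The sort kept cells with CD34 and CD45RA on the surface and removed cells with CD90, with high CD38 or with markers of mature blood lineages, a surface profile used for a lymphoid-primed progenitor fraction. Each cell was sorted into its own well of a 96-well plate and sequenced by Smart-seq2, a full-length method without molecular identifiers. Columns were at hand for 400 diagnosis cells and 411 relapse cells. Of these, 341 diagnosis cells and 323 relapse cells had at least 1000 genes detected and were kept. A kept diagnosis sample held 5.67e+07 ± 2.70e+07 reads and a kept relapse sample 4.68e+07 ± 2.05e+07 reads (SD, n = 5 patients), and the range over the 10 samples was 1.75e+07 to 8.85e+07 reads. The unit of replication was the patient. Reads were summed per patient and state, and relapse was compared with diagnosis within patients. Levels are given as CPM, the counts of a gene per 1e+06 counts of the sum.

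The first question was which genes differed between diagnosis and relapse in the same direction across patients. Among the genes that moved the same way in all 5 patients, the smallest unadjusted p belonged to SGK1, a kinase induced by glucocorticoids, at 56.1 ± 47.6 CPM at diagnosis and 265 ± 175 CPM at relapse (SD, n = 5; log2 fold change 2.29, SE 0.39). SKIL, an inhibitor of SMAD signalling, stood at 43 ± 32.4 and 365 ± 413 CPM (log2 fold change 2.35, SE 0.52). STAT4, a transcription factor of cytokine signalling, had a log2 fold change of 2.85 (SE 0.74), DUSP2, a nuclear phosphatase of MAP kinases, 2.59 (SE 0.76), and PDE4B, a phosphodiesterase that degrades cyclic AMP, 2.52 (SE 0.74). None of these genes passed the edgeR test after adjustment, while DESeq2 called all 5. In edgeR's quasi-likelihood test with the patient as a block, 0 of 7429 genes were called higher and 0 lower in relapse at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.991. At an unadjusted p under 0.05 there were 236 genes, 132 of them lower, where chance gives 371. DESeq2 called 14 genes higher and 8 lower, of which 11 moved one way in all pairs, and limma voom with quality weights called 0.

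Of the 12 genes with the smallest unadjusted p among those higher at relapse in 5 of 5 patients, the others were ABI2, CACUL1, TMEM41A, TSC22D2, MFF, COBLL1 and SBDSP1. Their log2 fold changes lay between 1.23 for CACUL1 and 4.23 for COBLL1 (SE 1.25). DESeq2 called ABI2, TMEM41A and COBLL1 of these, edgeR none. SBDSP1 is a pseudogene of SBDS, and its reads cannot be separated with certainty from those of the parent gene. Cells with an SGK1 read at equal depth made up 10.4% of diagnosis cells and 28% of relapse cells, and the corresponding shares for PDE4B were 33.4% and 60.9% (means over 5 patients).

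The 12 genes at the other end included 2 genes of DNA replication. MCM5, a subunit of the replicative helicase, stood at 220 ± 151 CPM at diagnosis and 89.8 ± 72.1 CPM at relapse (log2 fold change −1.48, SE 0.34), and RPA2, a single-stranded DNA binding protein, at 117 ± 41.5 and 38.2 ± 32.1 CPM (log2 fold change −2.16, SE 0.67). ARPC1B and ARPC4, subunits of the actin-nucleating Arp2/3 complex, had log2 fold changes of −1.17 (SE 0.35) and −1.38 (SE 0.42). The others were C10orf54, which encodes the immune checkpoint protein VISTA (−1.67), UBA1, the main ubiquitin-activating enzyme (−1.23), SLC25A37, a mitochondrial iron importer (−1.16), PARP4 (−1.44), HSH2D (−1.14), AHSA1, an activator of the HSP90 chaperone (−1.64), PCID2 (−1.63) and TPPP3 (−4.26, SE 1.25). All 12 were lower at relapse in 5 of 5 patients and none passed the adjusted threshold in edgeR, while DESeq2 called TPPP3. Single cells held large parts of some of these genes' reads, 18.6% for TMEM41A and DUSP2, 18.2% for STAT4, 14.5% for TPPP3 and 9.24% for SGK1.

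**Figure D1:**
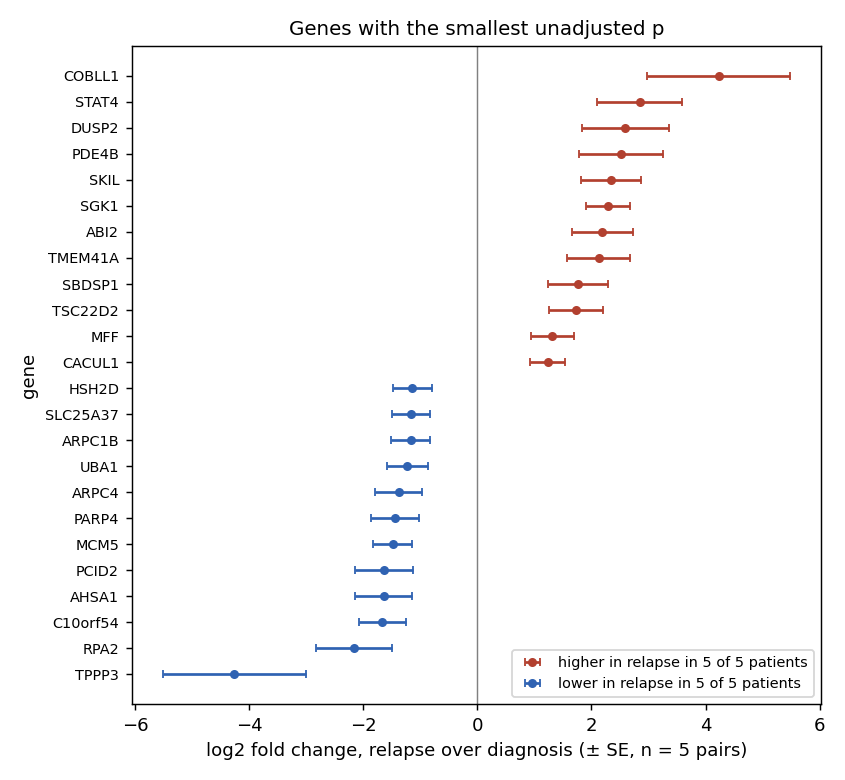
Log2 fold change of relapse over diagnosis (x axis) for the 24 genes with the smallest unadjusted p among genes that moved one way in all 5 patients. Points are edgeR estimates and bars are standard errors over 5 pairs; the values run from −4.26 for TPPP3 to 4.23 for COBLL1. With equal weight per cell the gene TPPP3 had −2.65 and the gene COBLL1 2.54. No gene passed the adjusted threshold in edgeR, and DESeq2 called 9 of them.

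Over all genes tested, changes within a patient had little in common between patients. Between 440 and 2204 genes per patient (median 989) differed by more than 4-fold between the patient's own diagnosis and relapse sums, a description without replicates. Of these, 0 genes did so in the same direction in all 5 patients and 13 in at least 4. The genes that moved in one direction in every pair numbered 505, 235 higher and 270 lower, or 6.80% of the genes tested where chance gives 6.25%. Across genes, the log2 changes of different patients had a median Pearson correlation of 0.03 over the 10 patient pairs (range −0.12 to 0.17) and a median Spearman correlation of 0.01. Among the 1000 most abundant genes the median Pearson correlation was also 0.03, but the highest pair reached 0.41 (Spearman 0.46). Genes are not independent replicates, so no p-value was given to these correlations.

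Ribosomal protein genes leaned one way. Of 81 tested, 80 had a positive log2 fold change, with a median of 0.55, and they took 10.6 ± 3.94% of reads at diagnosis and 13.8 ± 3.27% at relapse (SD, n = 5). RPL23 had a log2 fold change of 0.94 (SE 0.36) and RPL13 of 0.70 (SE 0.34). They were the only 2 of the 81 genes that were higher in 5 of 5 patients. Reads shared with processed pseudogenes make single ribosomal genes uncertain. The list was called higher by camera with a preset correlation between genes of 0.01 (adjusted p = 1.3e-11 over 33 lists). With an estimated correlation between genes, 0.824 for this list, the adjusted p was 0.779 and the call was lost. The list's median was above 0 in 3 of 5 patients and ranged from −0.47 to 1.58. Without either of 2 patients the median over the list fell to 0.32 and 0.31, with the call kept.

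Genes of the 17-gene stemness score (LSC17), a published prognostic signature of AML stem cells, were called higher at relapse with the preset correlation. The members were tested as a list without the weights of the score. The score itself was not computed, so a higher list is not a higher score. Of 9 tested, 8 had a positive log2 fold change (median 1.00, camera adjusted p = 0.0384, adjusted p = 0.703 with an estimated correlation). The list's median per patient ranged from −0.11 to 0.86 with a middle value of 0.02, so the fitted median lay above that of every patient. SMIM24 stood at 82.5 ± 65.2 CPM at diagnosis and 133 ± 86.7 CPM at relapse, and NGFRAP1 at 13.4 ± 28.8 and 23.1 ± 30.7 CPM, each higher in 4 of 5 patients. Without cells with B-cell markers the LSC17 median was 0.19 (adjusted p = 0.334) and the log2 fold change of SMIM24 went from 1.12 to 0.19, where the median of all genes was −0.17. Without cells with markers of any excluded lineage they were 0.00385 (adjusted p = 0.105) and 0.24, where the median of all genes was −0.38. The list also holds CD34, on which the cells were sorted. Genes of TGF-beta signalling and quiescence were likewise called higher, with 9 of 12 positive (median 0.52, camera adjusted p = 0.0384, adjusted p = 0.703 with an estimated correlation). Its members SKIL, the antiproliferative gene BTG2 (log2 fold change 1.46, SE 0.60, higher in 4 of 5 patients) and FOXO3, a transcription factor that restrains stem cell cycling (1.03, SE 0.43, higher in 5 of 5), had the smallest p. SKIL was the only member of the list past the threshold when adjusted over the list alone. The median of the quiescence list was 0.22 without B-marker cells (adjusted p = 0.0285) and 0.18 without cells of any excluded lineage (adjusted p = 0.157), with the same shifts of all genes. In cells thinned to equal depth LSC17 was no longer called (median 0.36, adjusted p = 0.14), nor was the quiescence list (median 0.43, adjusted p = 0.0697). With no replicate block the LSC17 median was 0.29 (adjusted p = 0.194), as it was in cells with at least 2000 genes (adjusted p = 0.233), and it ranged from 0.28 to 1.20 with a patient left out. The quiescence list took 0.54 ± 0.298% of reads at diagnosis and 0.486 ± 0.28% at relapse, higher in 3 of 5 patients. Its call was lost with no replicate block (adjusted p = 0.0647), and its median ranged from 0.27 to 0.78 with a patient left out. With 1 patient left out at a time, each list kept its call only once; in the remaining 4 fits the adjusted p ranged from 0.0549 to 0.162 for LSC17 and from 0.0586 to 0.211 for the quiescence list.

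Granulocyte-monocyte progenitor genes were called lower at relapse with the preset correlation. All 6 tested had a negative log2 fold change (median −1.48, camera adjusted p = 0.0384, adjusted p = 0.779 with an estimated correlation), and the list's median was below 0 in 4 of 5 patients. LYZ, the secreted lysozyme of the myeloid lineage, stood at 375 ± 440 CPM at diagnosis and 113 ± 86.8 CPM at relapse, and CST7, a myeloid cystatin, at 67.1 ± 66.3 and 36.8 ± 36.8 CPM. A single cell held 21.5% of all LYZ reads, and the log2 fold change of LYZ went from −1.74 to −0.93 without 1 patient. After thinning every cell to 100000 reads, 181 of 322 diagnosis cells and 111 of 309 relapse cells had reads from at least 3 of the 13 genes of this set. Averaged over patients this was 55.7 ± 26.2% at diagnosis and 32.6 ± 31% at relapse, lower in 4 of 5 patients (exact two-sided sign-flip p = 0.25, n = 5). Without thinning the shares were 62.8% and 43.6%. With no replicate block the list's median was −0.78 and its call was lost (adjusted p = 0.108). The list took 0.572 ± 0.615% of reads at diagnosis and 0.512 ± 0.895% at relapse. Cells with monocyte markers went the same way, 9.06 ± 9.75% and 3.31 ± 4.09%. Leaving out cells with B-cell markers ended the list's call (adjusted p = 0.127, median −1.64), as did leaving out cells of any excluded lineage (adjusted p = 0.187, median −1.43) and leaving out either of 2 patients (adjusted p = 0.196 and 0.216).

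Lymphoid progenitor genes were not called as a list by camera over all 5 patients, though without 1 patient they were called higher with the preset correlation (adjusted p = 0.0151, median 2.62). With an estimated correlation of 0.218 on all 5 patients the list's adjusted p was 0.779. DNTT, the template-independent DNA polymerase of early lymphoid cells, stood at 68.3 ± 106 CPM at diagnosis and 872 ± 1098 CPM at relapse, higher in 4 of 5 patients (edgeR unadjusted p = 0.0268, adjusted p = 0.991), and passed the threshold in DESeq2 (adjusted p = 0.00801). NOTCH1, a receptor of lymphoid commitment, had a log2 fold change of 2.08 (SE 0.83). Of the 4 list members tested 3 were positive (camera adjusted p = 0.272). Cells with at least 3 lymphoid progenitor markers numbered 29 of 322 at diagnosis and 75 of 309 at relapse, on average 7.26 ± 10.6% and 20.3 ± 23.6% (exact sign-flip p = 0.375, n = 5). Stem and multipotent progenitor markers were seen in 55.8 ± 29.5% of diagnosis cells and 46.6 ± 32.7% of relapse cells (exact sign-flip p = 0.50, n = 5). In that list MSI2, an RNA-binding regulator of stem cells, had a log2 fold change of 2.25 (SE 1.08) and GATA2, a stem cell transcription factor, of −2.76 (SE 1.57), and the list was not called (6 of 10 positive, adjusted p = 0.489).

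**Figure D2:**
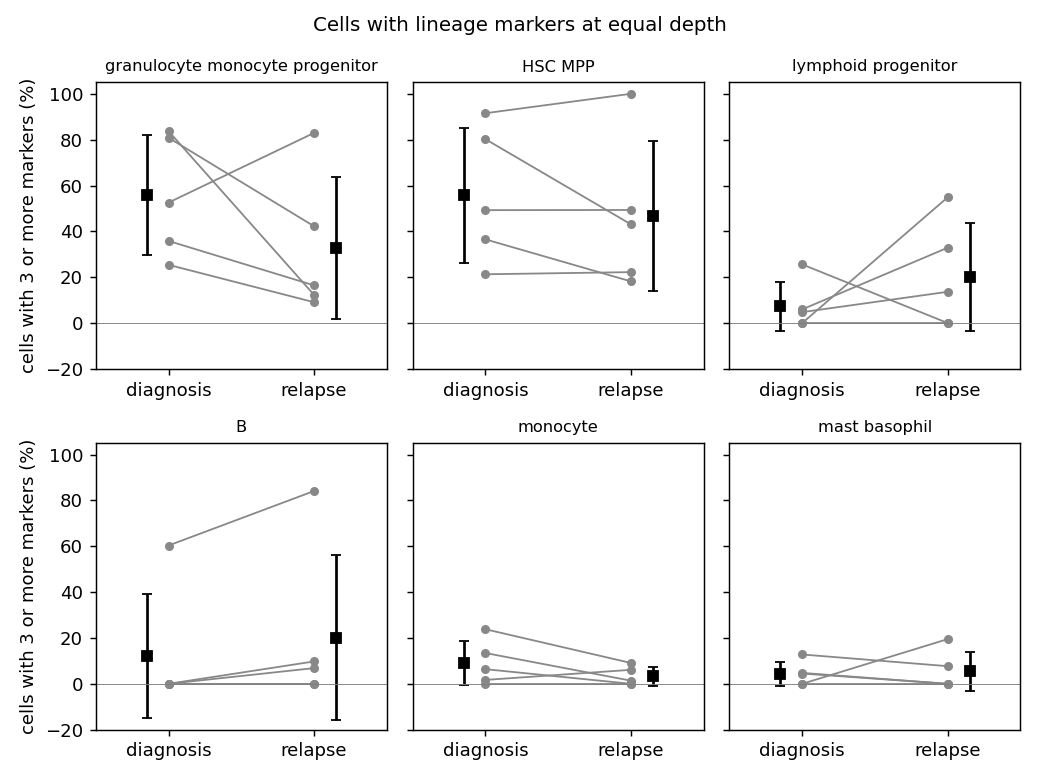
Share of cells with reads from at least 3 markers of a set (y axis, percent), in cells thinned to 100000 reads, at diagnosis and relapse. Grey lines join the samples of 1 patient, and black squares with bars are the mean and SD over 5 patients; granulocyte-monocyte progenitor shares were lower at relapse in 4 of 5 patients.

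Genes of MHC class II antigen presentation were called higher at relapse with the preset correlation, with 8 of 11 positive (median 0.84, camera adjusted p = 0.0384, adjusted p = 0.806 with an estimated correlation). HLA-DMA, which loads peptides onto class II molecules, stood at 454 ± 346 CPM at diagnosis and 773 ± 259 CPM at relapse, and CD74, the invariant chain, at 5257 ± 3051 and 8272 ± 3834 CPM. The list's median per patient ranged from −0.56 to 4.96, and without the patient at the upper end the adjusted p was 0.957 and the median 0.16. The call also ended without either of 2 other patients (adjusted p = 0.099 and 0.0586). With no replicate block the median was 0.61 and the call was lost (camera adjusted p = 0.0802). It was lost as well without a low count filter (adjusted p = 0.126) and with at least 5 reads in 25% of cells (adjusted p = 0.096). MHC class I genes were not called (6 of 13 positive, adjusted p = 0.705).

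Cells with markers of lineages that the sort should exclude were present in both states. Some single markers were read widely, such as TPSAB1 in 46.7% and LST1 in 57.4% of diagnosis cells (means over 5 patients). Having 3 markers of a set therefore does not establish a lineage. At least 3 B-cell markers were seen in 38 of 322 diagnosis cells and 50 of 309 relapse cells, on average 12.1 ± 27% and 20.1 ± 36% (exact sign-flip p = 0.25, n = 5), and the highest sample held 84.1%. All 38 diagnosis cells came from 1 patient. The B-cell list was not called by camera over all 5 patients (4 of 5 positive, adjusted p = 0.347). With the preset correlation it was called higher without 1 patient (adjusted p = 0.04, median 2.06) and on the mean over cells of log2(CPM + 1) (adjusted p = 0.00747). With an estimated correlation of 0.598 on the sums of all 5 patients its adjusted p was 0.806. MS4A1, which encodes CD20, was detected in 12.1% of diagnosis cells and 17.8% of relapse cells and was higher at relapse in 5 of 5 patients (edgeR unadjusted p = 0.00895, adjusted p = 0.991). It stood at 362 ± 809 CPM at diagnosis and 876 ± 1914 CPM at relapse. With SDs this far above the means, nearly all of it came from 1 patient in each state, so the direction in the others rests on low levels. Monocyte markers were seen in 28 and 10 cells, erythroid markers in 20 and 18, mast cell and basophil markers in 17 and 21, plasma cell markers in 3 and 14, dendritic cell markers in 7 and 17, natural killer cell markers in 5 and 1, stromal or endothelial markers in 2 and 1, and megakaryocyte markers in 1 and 0, at diagnosis and relapse. At least 3 T-cell or late neutrophil markers were seen in 0 of 322 and 0 of 309 cells thinned to 100000 reads. At that depth this allows shares of up to about 0.932% and 0.971% (3 divided by the number of cells, an approximate limit for counting error only). Without thinning, cells with T-cell markers were seen, on average 0.51% at diagnosis and 1.06% at relapse, and late neutrophil markers in 0 cells. Monocyte genes (1 of 3 positive, adjusted p = 0.689) and erythroid genes (3 of 3 positive, adjusted p = 0.15) were not called as lists.

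Metabolic lists were not called by camera on the sums of all 5 patients. On the mean over cells of log2(CPM + 1), however, oxidative phosphorylation (adjusted p = 0.000378), glycolysis (adjusted p = 4.93e-05) and fatty acid oxidation (adjusted p = 0.00747) were called lower with the preset correlation. Glycolysis was also called lower without 1 patient (adjusted p = 0.0363). An estimated correlation was used only on the sums of all 5 patients, where camera gave these lists adjusted p of 0.989, 0.779 and 0.779. Of 64 nuclear genes of oxidative phosphorylation 36 were positive (median 0.03, mean −0.04, adjusted p = 0.928). Glycolysis had 4 of 17 genes positive (median −0.34, adjusted p = 0.195), with TPI1 at −0.88 (SE 0.37) and PFKP at −1.07 (SE 0.46) on the log2 scale, each lower in 4 of 5 patients. Fatty acid oxidation had 4 of 14 positive (median −0.51, adjusted p = 0.126), the citric acid cycle 5 of 16 (adjusted p = 0.489), with FH, fumarate hydratase, at −1.90 (SE 0.83), and cholesterol synthesis 4 of 11 (adjusted p = 0.354).

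Survival, stress and signalling groups were not called by camera on the sums of all 5 patients. BCL2 family genes were split at 4 of 8 positive (adjusted p = 0.953), other apoptosis genes at 11 of 18 (adjusted p = 0.489), with the caspase inhibitor BIRC2 at a log2 fold change of 1.07 (SE 0.43), and p53 targets at 6 of 11 (adjusted p = 0.689). Interferon response genes had 17 of 30 positive (adjusted p = 0.689), but without 1 patient the list was called higher with the preset correlation (adjusted p = 0.00895, median 0.70). With an estimated correlation of 0.505 on all 5 patients its camera adjusted p was 0.988. Of the interferon genes IFIT5 was higher in 5 of 5 patients (1.75, SE 0.59) and ISG15 lower in 5 of 5 (−1.45, SE 0.88). A single cell held 25.8% of the reads of the gene IFIT5, whose change was 0.16 on the mean over cells of log2(CPM + 1), and that of the gene ISG15 was −0.74 without 1 patient. Immediate-early and heat shock genes had 11 of 19 positive (adjusted p = 0.489), with the gene NR4A1 at 2.60 (SE 1.11), but 0.71 with no replicate block, 0.97 on the mean over cells, 5.49 without cells of any excluded lineage and 1.79 to 3.50 with a patient left out. Chemokines and their receptors had 1 of 6 positive (adjusted p = 0.347), and the positive member was CXCR4, the marrow homing receptor (2.08, SE 0.97, higher in 3 of 5 patients, 1.26 for the gene CXCR4 without 1 patient). NF-kappaB targets (9 of 14, adjusted p = 0.689), hypoxia genes (6 of 10, adjusted p = 0.689) and genes of the unfolded protein and integrated stress responses (6 of 13, adjusted p = 0.998) were likewise not called, and PDIA6 of the last group stood at −1.01 (SE 0.44).

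Proliferation, drug handling and surface target genes gave no call by camera on the sums of all 5 patients. S-phase genes had 11 of 22 positive (adjusted p = 0.589), and MCM5 was the only member past the threshold when adjusted over the list alone. G2 and M phase genes had 7 of 17 positive (adjusted p = 0.689) and MYC and ribosome biogenesis genes 8 of 20 (adjusted p = 0.489). Drug transporters had 2 of 4 positive (adjusted p = 0.689) and cytarabine metabolism genes 4 of 10 (adjusted p = 0.536). The nucleoside importer SLC29A1, through which cytarabine enters cells, stood at 57.9 ± 77 CPM at diagnosis and 17.5 ± 15.8 CPM at relapse, lower in 4 of 5 patients, with a log2 fold change of −2.51 (SE 1.60) that did not pass the test (edgeR unadjusted p = 0.152, adjusted p = 0.991). Epigenetic regulators had 11 of 17 positive (adjusted p = 0.347). AML surface targets had 5 of 14 positive (adjusted p = 0.347) and were called lower without 1 patient with the preset correlation (adjusted p = 0.0355, median −0.39). With an estimated correlation of 0.211 on all 5 patients the list's adjusted p was 0.806. Its member IL1RAP stood at −1.87 (SE 1.03, lower in 5 of 5 patients) and CD33 at −1.17 (SE 0.68, lower in 4 of 5). The gene IL1RAP stood at −1.12 without 1 patient and −3.60 without B-marker cells, and with a patient left out the gene CD33 ranged from −1.75 to −0.76 and the gene SLC29A1 from −3.48 to −1.55. Of the genes behind the sort, CD34 had a log2 fold change of 0.24 (SE 0.31), CD38 of 0.06 (SE 0.81) and PTPRC, which encodes CD45, of −0.40 (SE 0.36); as a list they were not called (2 of 3 positive, adjusted p = 0.986). Over the 33 lists tested, 0 were called with an estimated correlation and 0 by fry, with smallest adjusted p of 0.703 and 0.432 (limma, patient as a block). The median and the mean log2 fold change differed in sign for oxidative phosphorylation, p53 targets, interferon response, NF-kappaB targets, the unfolded protein response, drug transport and the sort genes, and for the BCL2 family the test pointed down while both were above 0.

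**Figure D3:**
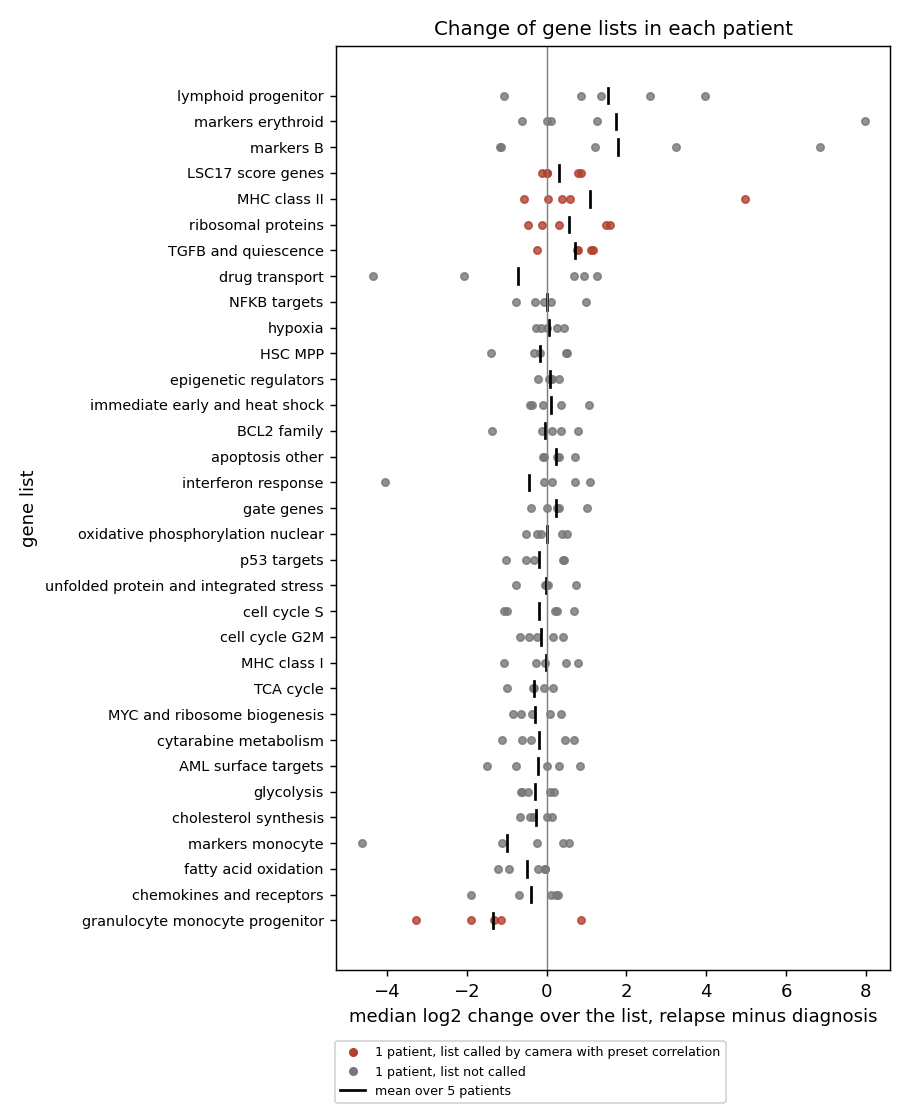
Median log2 change over each gene list, relapse minus diagnosis (x axis), for each of 5 patients (points) with the mean over patients (black bars). The 5 lists called with the preset correlation are in red, and each of them has patients on both sides of 0, as for ribosomal proteins from −0.47 to 1.58.

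The series title asks about heterogeneity. Of 3 measures taken in cells thinned to 100000 reads, the correlation between cells of a sample bears on it most directly. A lower correlation can be more heterogeneity or more technical noise. Genes detected per cell were 2472 ± 501 at diagnosis and 2373 ± 958 at relapse (SD over 5 patients of the median over cells), higher at relapse in 2 of 5 patients (exact sign-flip p = 0.688, n = 5). Without thinning the values were 2999 ± 561 and 2871 ± 998. The median Spearman correlation between cells of a sample was 0.337 ± 0.0389 at diagnosis and 0.348 ± 0.0309 at relapse, higher in 4 of 5 patients (exact sign-flip p = 0.25, n = 5). Cells with at least 3 G2 and M phase genes made up 92.7 ± 7.88% and 82.3 ± 13.5%, higher in 0 of 5 patients (exact sign-flip p = 0.125, n = 5). This share was close to its ceiling and was not read as a share of dividing cells. With 2 or more of 10 mitotic genes, a measure chosen after the data were seen, the shares were 10.3 ± 14.3% and 8.02 ± 6.57% (exact sign-flip p = 0.75, n = 5). With 5 pairs that all differ no such test can go below p = 0.0625, and pairs with equal values raise this limit. It was 0.125 for the share with G2 and M phase genes, with 1 tied pair, and 0.25 for that with B-cell markers, with 2, so both were at the smallest p their pairs allow.

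Diagnosis and relapse cells of the same patient mixed less than their numbers would give, in 5 of 5 patients. Among the 10 nearest neighbours of a diagnosis cell, the share of relapse cells divided by the share expected from the cell numbers had a median of 0.159 over patients (range 0.118 to 0.357), where 1 is full mixing. For relapse cells the median was 0.0881, and the range from 0.0107 to 0.761 was wide, up to relapse cells with many diagnosis cells as neighbours. With the state labels shuffled within patients the medians were 0.963 and 0.998. Each patient had a single sample per state, no test was made, and the labels used here do not give the plate of a cell, so plate and state cannot be separated in this measure.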

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

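The analyses at equal depth, with an estimated correlation and with each patient left out were fixed before the data were examined, but what they would show for each pattern was set down after their values were seen, as it was for the splits of samples. The analyses without B-marker cells and the CD34 comparison in other patients were chosen after the results were seen. The CD34 comparison over 4 samples together was set down before its result was seen. A sample or patient was singled out where its distance to the nearest of the other 4 exceeded 0.71 of the range of the 5 values (Dixon's criterion). This held in 18 of 122 groups of 5, where chance gives about 6.1.

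The share of spike-in reads was far higher in 1 patient than in the others, with a gap of 0.992 of the range at diagnosis and 1.0 at relapse. Median genes per kept relapse cell were highest in 1 patient (gap 0.804 of the range), also at equal depth (0.768). The share of cells with B-cell markers was highest at diagnosis (1.0) and at relapse (0.884) in the same patient as the share of spike-in reads. The share with lymphoid progenitor markers stood apart at diagnosis (0.767), and at relapse those with dendritic cell (0.861) and plasma cell markers (0.90). The shares with natural killer cell and stromal markers at relapse and with megakaryocyte markers at diagnosis were flagged too (1.0). Each was a single cell, which can come from only 1 patient, so these flags do not describe a patient. Among changes from diagnosis to relapse, 1 patient stood above the rest for the MHC class II list (0.792), the erythroid list (0.781) and HLA-DMA (0.778), and 1 patient stood below the rest for the interferon response list (0.776), ISG15 (0.742) and IL1RAP (0.753).

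Ribosomal protein genes were called higher at relapse with the preset correlation, 80 of 81 positive, with a median log2 change of 0.55 that fell to 0.32 and 0.31 without either of 2 patients. Unequal weight of deep and shallow cells is argued against. In cells thinned to equal depth the median was 0.54 and the list was still called. Thinning draws reads at random and keeps each gene's expected share, so it cannot test an effect of depth on those shares. Spread between patients in genes that move together remains open and may be enough, since the adjusted p was 0.779 with an estimated correlation of 0.82 and the list's median was below 0 in 2 of 5 patients. A change with the state and a difference between plates were not tested.

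MHC class II genes were called higher at relapse with the preset correlation (8 of 11 positive, adjusted p = 0.0384) but not with an estimated correlation (adjusted p = 0.806), and B-marker cells were seen in both states. The MHC class II change rested largely on 1 patient, without whom the adjusted p was 0.957 and the median fell from 0.84 to 0.16, while leaving out others kept the median at 0.93 or above. B-marker cells as its whole source are argued against, since without them the list's median was 0.73 and the list was still called (adjusted p = 0.026). Whether B-marker cells are mature B cells, which a sort on CD34 and without lineage markers would remove, cannot be told apart from leukaemic cells with B-cell transcripts for the patient with most of them. This patient also had the highest spike-in share, with a median of 22.8% at diagnosis and 67.7% at relapse over deposited cells. It also had the lowest share of relapse cells kept, 55.1%. CD34 reads were seen in 20.5% of the 88 B-marker cells and in 80.5% of the other cells of the same 4 samples, as set down for mature B cells, but this mixes samples and the share was lower in only 2 of the 4; in the patient with most B-marker cells it was 8.0% (exact 95% interval 2.99 to 16.6%) against 31.2%, while in 2 other patients 92.3% of 13 B-marker cells carried CD34 reads against 91.5% of the other cells, which argues against mature B cells there.

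The list of granulocyte-monocyte progenitor genes was called lower at relapse with the preset correlation but not with an estimated correlation (adjusted p = 0.779). Unequal weight of deep and shallow cells is argued against for the size of the change. The median log2 change was −1.47 at equal depth and −1.36 with equal weight per cell, next to −1.48 in all reads. At equal depth the list was still called by camera (adjusted p = 0.0464). With equal weight per cell the call was lost (camera adjusted p = 0.0609). An effect of depth on each gene's share of reads cannot be tested by thinning. Without cells with B-cell markers the median was −1.64 and the adjusted p 0.127, so the call ended with fewer cells although the change was no smaller, which leaves that explanation open. Chance differences between 5 patients may also account for it, since the share of cells with these genes gave an exact sign-flip p = 0.25.

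The 0 genes called give nothing to set against chance, and all 100 of 100 splits of the 10 samples into 5 and 5, drawn from 126, gave at least as many. The highest of the other splits called 188 genes and left patients unparted. With the patient as a block, an unparted pair carries no information on the split, so such a fit rests on fewer patients. The 14 drawn splits that parted all 5 pairs, the real one included, called 0 genes. The cause of the 188 calls was not tested. For lists, 42 of 100 splits gave 5 or more, with a highest other value of 10, and 6 of the 14 that parted all pairs did so, with a highest other value of 7, so chance is not excluded for the number of lists called.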

How the results depend on the processing

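Of the 54 genes named, 51 kept their direction under all alternatives run, and 11 passed the threshold under some alternative. Kept directions were partly fixed by the choice of genes, since 12 per direction were taken for moving one way in all pairs of these sums. Sizes are the more telling check. The sizes of the named genes' changes held less well: 45 moved by over 1.5 times under some alternative, 34 on the mean over cells of log2(CPM + 1), 21 without cells of any excluded lineage, 14 with a patient left out, 11 with no replicate block and 11 with equal weight per cell. DESeq2 called 14 genes higher and 8 lower, 18 of these 22 with an unadjusted edgeR p under 0.05; without a low count filter 1 gene, MS4A1, was called higher (adjusted p = 0.00873). The fitted log2 fold change of the gene MS4A1 depends on the model, 7.54 there but 1.27 with no replicate block, 1.97 with voom quality weights and 2.31 with equal weight per cell. All other alternatives, including the fit with no replicate block and each patient left out, called 0 genes; the cause was not tested. In simulated sums 22% of 4-fold changes were recovered with the observed dispersion and 98% with a dispersion divided by 5; read depth was varied only by thinning, which also gave 0 genes. The median log2 change of all genes moved from −0.01 to 0.17 without a filter, −0.11 with the mean over cells of log2(CPM + 1), −0.17 without B-marker cells and −0.38 without cells of any excluded lineage, so single changes there are relative to that shift.

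The number of lists called fell from 5 to 1 with no replicate block, that is without the pairing by patient. It was 1 without a low count filter, 1 with at least 5 reads in 25% of cells, 3 in cells thinned to equal depth, 2 with equal weight per cell, 0 with an estimated correlation and 0 with fry. It was 3 without cells with B-cell markers and 2 without cells with markers of any excluded lineage, both added after the data were seen. It was 7 from the mean over cells of log2(CPM + 1), 4 of them other lists: oxidative phosphorylation, glycolysis, fatty acid oxidation (lower) and B-cell markers (higher). Leaving out each patient in turn gave 9, 2, 1, 2 and 3 lists; the 9 include glycolysis and AML surface targets (lower) and interferon response and B-cell markers (higher), and the 3 lymphoid progenitor genes (higher). Ribosomal proteins were called in 21 of 23 alternatives, MHC class II in 14, granulocyte-monocyte progenitor genes in 12, quiescence genes in 10 and LSC17 in 8, each in its original direction. The cause was not tested beyond what the estimated correlation shows.

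The gene CD34 changed sign to −0.69 as the mean over cells of log2(CPM + 1), −0.48 without B-marker cells and −0.56 without cells of any excluded lineage. The gene CD38 changed sign to −0.94 with no replicate block (pairing removed), −0.61 with equal weight per cell, −0.48 as the mean over cells of log2(CPM + 1) and with voom quality weights, −0.44 without B-marker cells and −0.49 without cells of any excluded lineage, and ranged from −0.55 to 0.56 with a patient left out. The gene CD33 changed to 0.12 without cells of any excluded lineage.

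The difference in genes detected per cell ranged from −347 to 160 with a patient left out. Its mean of −98.8, that of −10.4 percentage points in cycling cells (3 or more G2 and M genes) and that of 0.0115 in similarity are the same with no replicate block, and the unpaired exact permutation p were 0.841, 0.19 and 0.619, so the block changed no call there. Similarity was higher at relapse in 5 of 5 patients in cells with at least 2000 genes (exact p = 0.0625, n = 5, the smallest possible). The mixing ratio of diagnosis cells, 0.159, was 0.306 with 20 neighbours, 0.102 with 5, 0.264 with 30 components and 0.0938 with 10; that of relapse cells, 0.0881, was 0.0513 with at least 2000 genes and 0.0568 with 5 neighbours.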

Other observations

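The marker overlaps and the 2 genes in this part were chosen after the data were seen, while the DESeq2 test was planned. Stem and myeloid progenitor markers were often read in the same cell. At equal depth 207 of 631 cells, 32.8% (exact 95% interval 29.2 to 36.6%), had at least 3 markers of stem and multipotent progenitors and at least 3 of granulocyte-monocyte progenitors. Granulocyte-monocyte markers were seen in 58.6% of the 353 cells with the stem set and in 30.6% of the 278 cells without it. Within samples with at least 5 cells of each kind, the share was higher in cells with the stem set in 6 of 9 samples, so the pooled difference also holds differences between samples. Of the cells with lymphoid progenitor markers 63.5% had the granulocyte-monocyte set, against 42.9% of the others, and the share was higher in 3 of the 4 samples with enough cells. These are counts of cells with no test over patients, and no doublet caller was run.

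Among the genes DESeq2 called that the rule for named genes did not take, 2 are given here. CRIP1, a LIM domain protein, stood at 520 ± 457 CPM at diagnosis and 280 ± 425 CPM at relapse, lower in 4 of 5 patients (DESeq2 adjusted p = 0.00349, edgeR adjusted p = 0.991). RGS2, a regulator of G protein signalling, stood at 119 ± 84.9 and 451 ± 258 CPM, higher in 4 of 5 patients (DESeq2 adjusted p = 0.0169, edgeR adjusted p = 0.991).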
